A study of Bacillus subtilis with 8 samples.

How the data were processed

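Genomic DNA from whole cells of Bacillus subtilis strain PY79, a laboratory strain of this Gram-positive soil bacterium, was sequenced in 8 samples. Per the labels' protocols, cultures were started at an optical density (OD) of 0.05, grown at 30 °C with shaking and treated at an OD of 0.2 with 25 mM hydroxyurea or with water as the vehicle. Hydroxyurea inhibits ribonucleotide reductase, the enzyme that makes deoxyribonucleotides. Cells were collected at 1 hour and at 2 hours.

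The authors deposited a single table for the whole series, in which each line is a bin of the chromosome. Its position columns, headed as start and stop, give the bin edges in base pairs. That the start is counted from 0 was read from the values, because the headers do not state it. The submitters' processing notes name BWA, SAMtools and bedtools, without versions or the role of each. The name the authors gave the deposited table mentions removal of duplicates and carries the tag q20, which by its form would be a quality minimum of 20; what it was applied to is not stated. The table names its sequence PY79. The genome build and the other settings of the alignment are not given in the sources used here.

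The table also holds 8 columns of values that were not used. That each belongs to 1 library is inferred only from their number, which equals that of the samples. The names of these columns are serial codes that appear in none of the labels. No column could therefore be given to a sample, to a treatment or to a time. Assigning them by their order would have been a guess that no label bears out, and assigning them by the shape of the values would have presumed the outcome that the comparison is meant to measure. For this reason the depth per sample, the ratio of origin to terminus reads, the slopes along the replication arms and the ratios of prophage to flanking reads are not reported here.

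The position columns were read with Python 3.11.15. The number of bins, their lengths, and the gaps, overlaps and repeats between neighbouring bins were computed from them. Positions are given counted from 1. A gene table of another strain, 168, was at hand with 4536 genes. Because it belongs to a different genome sequence, its coordinates were not used, and no bin was given a gene name.

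The samples fall into 4 groups by treatment and time, with 2 replicates each, per the labels. The tests planned before the data were examined included a quasi-likelihood test on read numbers per feature, also in larger windows. They also included exact permutation tests on ratios and arm slopes per library, and tests of fixed gene lists. The plan named features at the origin and terminus, those with the largest changes or local deviations, and the PBSX prophage and skin element regions. It also named a fixed set of genes of replication, DNA damage, ribonucleotide reductase, and oxidative and iron stress. None of these tests was run, and none of their alternative settings could be computed. The layout of the bins alone was computed again with the start read as counted from 1.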

Results

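The series addressed how hydroxyurea treatment bears on the genomic DNA of growing Bacillus subtilis PY79 cells, by whole genome sequencing. The labels describe 8 samples in 4 groups. There were 2 samples of cells treated with 25 mM hydroxyurea for 1 hour and 2 treated for 2 hours. Each time had 2 control samples that received water.

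The deposited table divided a sequence named PY79 into 4034 bins. The bins ran from position 1 to position 4033459 and covered 4033459 bp. Of these bins, 4033 were 1000 bp long. The remaining bin was the last by position, started at position 4033001 and held 459 bp. There were 0 gaps, 0 overlaps and 0 repeated bins, so each position from the first bin to the last lay in a single bin. The end of the last bin was not checked against a PY79 genome sequence. The lines of the table were not in chromosome order throughout, with 3 places where a bin was followed by one nearer the start of the sequence.

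The design implies a comparison of hydroxyurea with water at 1 hour, the same comparison at 2 hours, and a comparison of the difference between these times. None of them was made. The 8 value columns of the table carry codes that the sample labels do not explain, and no column could be placed in a treatment or time group. No difference in read depth along the chromosome, at the origin, at the terminus or at any prophage, is therefore reported for any group.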

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

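No comparison between groups was computed, so none of the normalizations, filters, window sizes or left-out replicates meant for them was run. The layout of the bins was computed again under 1 other setting, chosen after seeing the data, in which the start column was read as counted from 1 with the end included. Under that reading 4033 bins shared a base with the next bin, against 0 with the start counted from 0, and 0 bins were 1000 bp long, against 4033. It would also put the first bin at a position before the sequence begins. Both counts follow by arithmetic from bins that adjoin without gaps, so they are no test of robustness. They say nothing about any effect of treatment. No paired analysis was possible because the value columns carry no replicate number and could not be matched to the samples.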
